A study of Homo sapiens with 8 samples.

How the data were processed

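Total RNA from Caco-2 clone TC7 cells was labelled with the Affymetrix whole-transcript sense target protocol and hybridised to expression arrays, 4 for CRTC1 plasmid and 4 for empty vector, per the labels. The deposited values are log2 expression values, 1 per probe set and array, ranging from about 0.83 to 12.87. Partek is named in the submitters' processing notes without a version or a role. Background correction, summarisation and normalization are not given in the sources used here. The 8 columns had nearly the same distribution, with medians from 4.11 to 4.15, and the scale was read from the values. A change in total RNA per cell, or a shift shared by most genes, would not be seen in values scaled in this way. The table held no detection calls, so dim probe sets could not be separated from background.

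The table held 23786 probe sets. Gene names came from the platform annotation, which can be old, and were updated through Entrez identifiers with the RefSeq table of assembly GRCh38.p14, which matched all 22458 symbols. Of the probe sets, 22458 had 1 gene symbol, 0 had several and 1328 were unnamed here and were left out of the main test. Each named gene had 1 probe set. No genomic positions are given, since the build behind the probe sets is not given in the sources used here.

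The groups were compared with limma 3.58.1 in R 4.3.3. A linear model with 1 coefficient per group was fitted to the log2 values of all 8 arrays, with empirical Bayes moderation and no block. P-values were adjusted over 22458 genes by the Benjamini-Hochberg method, with a threshold of 0.05. A looser count used an unadjusted p under 0.05 and at least a 1.5-fold difference. Single values were also tested by exact two-sided permutation of the 4 and 4 arrays.

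Before the data were examined, 29 gene lists holding 512 genes were fixed. Of these genes 48 had no probe set named here and 464 were measured. The 29 lists covered CREB and CRTC targets and components, signalling, stress, cell cycle, metabolism and markers of other cell types. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 29 lists. Beside it stood camera with an estimated correlation and fry, a rotation test of whether a list's genes move in the same direction. Both used the main fit, without the replicate number. Of the lists, 7 passed with the preset correlation, 5 higher and 2 lower, 0 with the estimated correlation (lowest adjusted p = 0.341; 1 list at an unadjusted p under 0.05) and 0 with fry (lowest adjusted p = 0.187; 4 lists at an unadjusted p under 0.05). List members were also adjusted over the list alone, and the mean of each list was computed per array. In 3 of the 29 lists a member passed over the list alone, but 0 members passed when adjusted over the fixed lists together. The median of each list past the threshold was also set among those of 10000 random lists of the same size matched on mean level.

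The rule for named genes was fixed with the design. It took CRTC1, CRTC2, CRTC3 and CREB1. It then took up to 12 genes per direction with the largest change among those past the threshold with no overlap between the groups, filled up by the smallest p and given as values that did not pass. Unnamed loci, small RNAs and olfactory receptor genes were counted but not named there. Last, it took up to 4 members with the smallest p from each list past the threshold and 1 from every other list.

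The steps were tested on simulated data with the real genes' means and spread, with 200 genes changed in each of 10 runs. Of simulated changes of 1.5-fold, 47.5% ± 5.35 (SD over 10 runs) were recovered, of 2-fold 82.2% and of 4-fold 98.5%, with 8.1 false calls per run. These rates hold for data with that many changed genes, since fewer would make the adjusted threshold stricter. A list shifted by 0.3 on the log2 scale was recovered in 10 of 10 runs by camera at the preset correlation. Smaller shifts were not simulated, so recovery at the smaller list medians given below is unknown. Genes were simulated as independent, so the simulation does not test lists whose genes vary together between arrays. Alternatives covered a replicate block, other normalization and centring, filters on dim genes, other variance models, array weights, all probe sets, other list tests, and leaving out each array and each replicate number.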

Results

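Gene expression was measured in Caco-2 clone TC7, a human epithelial colon cancer line, after overnight transfection with an expression plasmid for CRTC1 or with the matching empty vector. CRTC1 is a coactivator that binds the transcription factor CREB and raises transcription of its target genes. Each transfection used 200 ng of plasmid, and each group had 4 arrays hybridised with labelled total RNA. The deposited log2 values covered 23786 probe sets on all 8 arrays, and the array medians lay between 4.11 and 4.15. Correlations between arrays ranged from 0.987 to 0.992 across genes, which are not independent replicates. The precision of each value was limited by the number of arrays, n = 4 in each group for every gene and list below. The labels do not say that the arrays came from separate cultures, so p-values measure the spread between these samples, which may be technical.

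The comparison asked which transcripts differ between Caco-2 cells given CRTC1 and cells given empty vector. CRTC1 itself (Entrez Gene 23373) rose from a log2 expression of 5.90 ± 0.407 (SD, n = 4) to 11.87 ± 0.457 (SD, n = 4). The log2 change was 5.97 with a standard error of 0.25, a 62.6-fold difference with a 95% interval of 42.1 to 93.2. The sources used here do not give the sequence the plasmid carried, which of the probes it covers or whether plasmid DNA was removed before labelling, so the fold is that of all signal on the CRTC1 probe set. Per array, CRTC1 lay at 12.52, 11.78, 11.70 and 11.46 in the transfected cells and between 5.48 and 6.30 in the controls. It was the 1 gene of 22458 past the threshold in limma's moderated test (adjusted p = 3.11e-05). The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 arrays allow. The related coactivators CRTC2 and CRTC3 differed by 0.07 (adjusted p = 0.942) and 0.19 (adjusted p = 0.852) on the log2 scale, and CREB1, which encodes CREB, by 0.10 (adjusted p = 0.907). Without CRTC1 replicate 1 the log2 change of CRTC2 was -0.04.

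**Figure D1:**
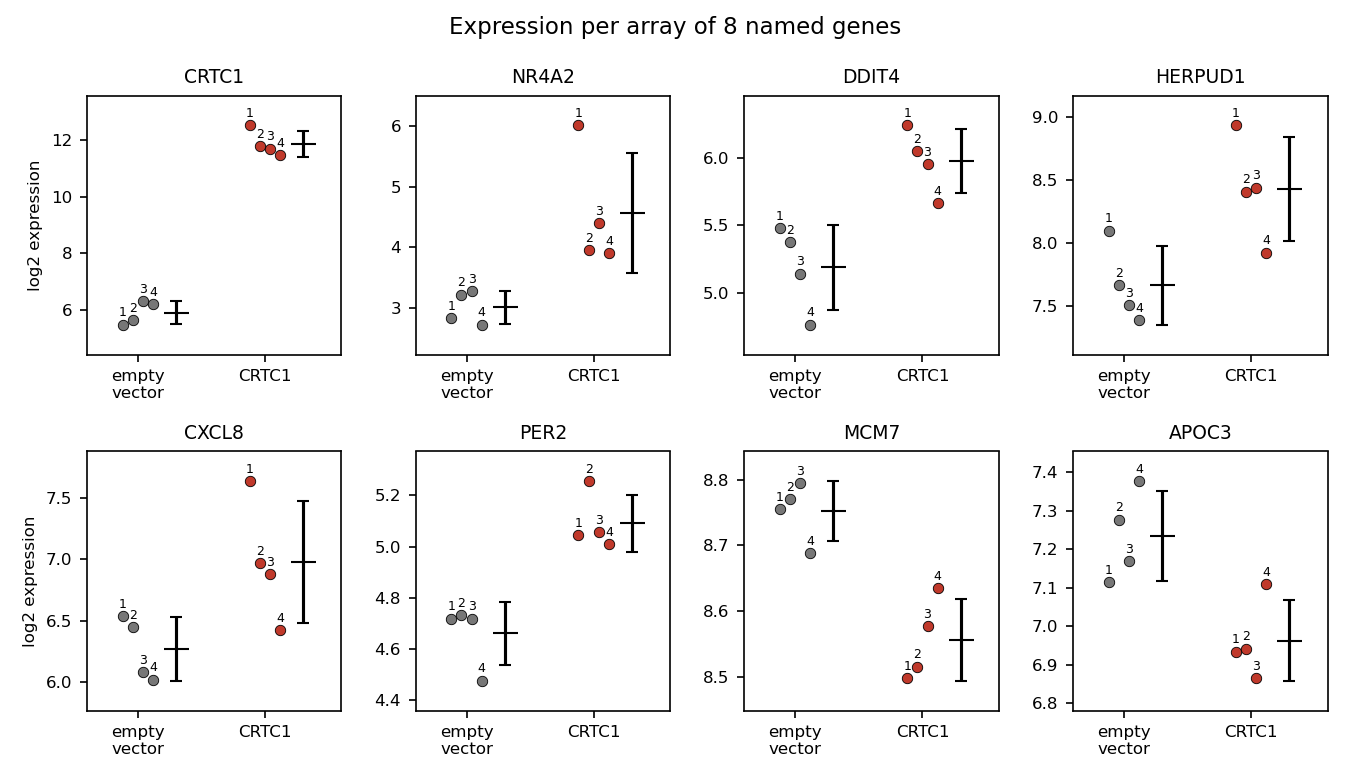
Log2 expression of 8 named genes on each array, empty vector in grey and CRTC1 in red, with the replicate number above each point and the group mean ± SD (n = 4) beside the points. CRTC1 reached 11.46 to 12.52 in transfected cells against 5.48 to 6.30 in controls, and NR4A2 was highest on CRTC1 replicate 1, at 6.01.

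No gene other than CRTC1 passed, and the next lowest adjusted p was 0.177. With limma at an unadjusted p under 0.05 there were 1333 genes, 719 higher and 614 lower with CRTC1, where 1123 would be reached by chance. Of these, 81 also differed at least 1.5-fold, 46 higher and 35 lower. The count of 81 was 154 without empty vector replicate 1, 135 without CRTC1 replicate 1 and 140 without CRTC1 replicate 4. The 2 groups of arrays did not overlap in 839 genes, a share of 3.74% where chance gives 2.86%.

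The genes with the smallest p-values after CRTC1 are given as values that did not pass. On the higher side H3C4, a histone H3 gene, had a log2 change of 0.94 (adjusted p = 0.197). It belongs to a family of near-identical histone genes, so its own level is uncertain. The zinc finger gene ZNF75A had a change of 0.62 (adjusted p = 0.672). The histone demethylase gene KDM3A had 0.40, the clock gene PER2 0.43, and DDIT4, an inhibitor of mTOR signalling, 0.79. FRRS1L (0.58), PLSCR2 (0.63), SPACA1 (0.36), PAGE5 (0.82), ZNF214 (0.38) and PABPC4L (0.56) completed the higher side, and all of these except H3C4 and ZNF75A had an adjusted p of 0.837. On the lower side the pseudogene WFDC21P had a log2 change of -0.60 (adjusted p = 0.177) and KRABD2 of -0.76 (adjusted p = 0.500). The adaptor complex gene AP4M1 had -0.42, the nucleotide receptor gene P2RY6 -0.47, the R-spondin receptor gene LGR6 -0.61 and the endocytic recycling gene EHD1 -0.51. GOLGA2P11 (-0.53), BRWD1-AS1 (-0.50), VSX1 (-0.46), CCDC78 (-0.43), SIGLEC8 (-0.48) and LYVE1 (-0.49) followed, and each lower gene after KRABD2 had an adjusted p of 0.837. Of the 24 genes named in this way, CRTC1 included, 15 had a mean level under the median of all genes, 4.16.

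**Figure D2:**
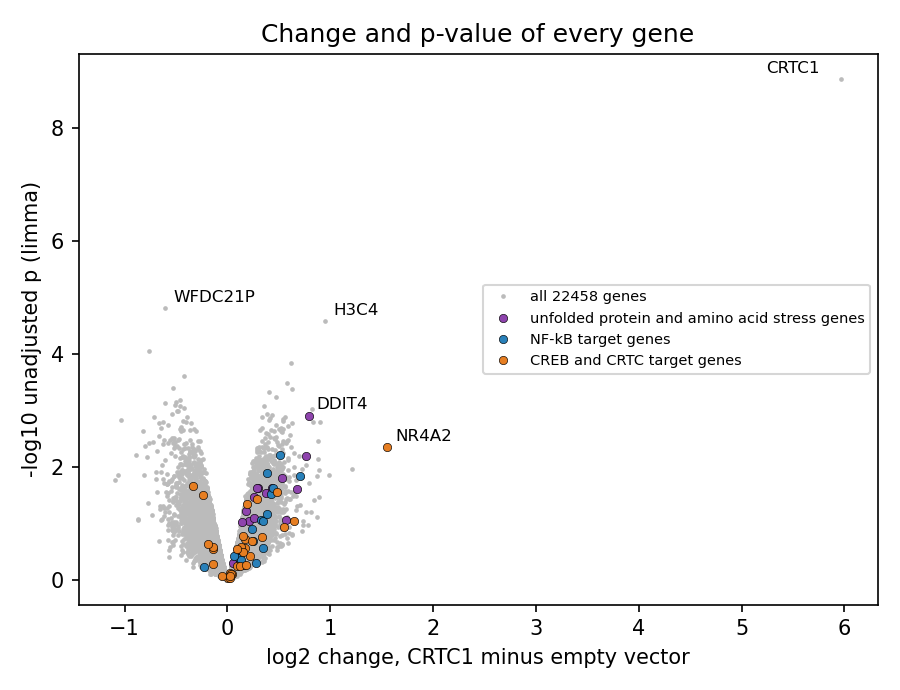
Log2 change, CRTC1 minus empty vector, against -log10 of limma's unadjusted p for all 22458 genes, with members of 3 fixed lists in colour. CRTC1 stands apart at 5.97, and NR4A2 follows at 1.55.

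CREB and CRTC target genes passed in camera as higher with CRTC1 (adjusted p = 0.0437), but not with an estimated correlation (adjusted p = 0.830 with an estimated correlation). Of 31 measured members 24 were higher and 7 lower, with a median log2 change of 0.13. The largest difference was that of NR4A2 (Entrez Gene 4929), a nuclear receptor induced by cAMP signalling, whose level went from 3.02 ± 0.272 to 4.57 ± 0.985 (SD, n = 4). Its log2 change of 1.55 (standard error 0.42, adjusted p = 0.837) was the second in size after CRTC1 but did not pass. NR4A2 lay at 6.01 on CRTC1 replicate 1, all 4 CRTC1 arrays were above all 4 control arrays, and without CRTC1 replicate 1 its log2 change was 1.07. At an unadjusted p under 0.05 were 4 higher and 2 lower members, among them the growth factor gene EREG at 0.48, the neuropeptide precursor gene VGF at -0.34 and the somatostatin gene SST at -0.23. No member passed over all genes or adjusted over the list alone, where the lowest adjusted p was 0.140. The list mean per array was 4.285 ± 0.168 with CRTC1 against 4.133 ± 0.04575 with empty vector (SD, n = 4). All 4 CRTC1 arrays lay above all 4 control arrays (exact permutation p = 0.0286, 0.237 after adjustment over the fixed lists). The margin was narrow, with CRTC1 replicate 2 at 4.1648 and empty vector replicate 3 at 4.1585. CRTC1 replicate 1 was highest, at 4.53. Among random lists matched on level the median lay at percentile 99.99. Genes of random lists need not vary together, so this percentile addresses only a trend with level. The camera call was lost without CRTC1 replicate 1 (adjusted p = 0.647), CRTC1 replicate 4 (0.0559), or empty vector replicate 1 (0.0563), 2 (0.188) or 3 (0.0653). The median was 0.05 without CRTC1 replicate 1, and 0.07 without CRTC1 replicate 4 or without empty vector replicate 1.

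The list of unfolded protein and amino acid stress genes passed in camera as higher with CRTC1 (adjusted p = 9.46e-11), but not with an estimated correlation (adjusted p = 0.728 with an estimated correlation). All 18 members were higher, 9 of them at an unadjusted p under 0.05, and the median log2 change was 0.27. DDIT4 went from 5.19 ± 0.316 to 5.98 ± 0.240 (SD, n = 4), a log2 change of 0.79. HERPUD1, a component of ER-associated protein degradation, had a change of 0.76, the stress gene SESN2 0.53 and HSPA5, which encodes the ER chaperone BiP, 0.29. DDIT4 was the 1 member to pass adjusted over the list alone (adjusted p = 0.0225), and no member passed over all genes or over the fixed lists together. The mean of the list per array was 7.46 ± 0.210 with CRTC1 and 7.11 ± 0.189 with empty vector (SD, n = 4). That difference of 0.34 had an exact permutation p of 0.0571 (0.237 after adjustment over the 29 lists), and 3 of 4 CRTC1 arrays lay above all control arrays. CRTC1 replicate 1 was the highest array, at 7.74, and empty vector replicate 1 the highest control, at 7.35. CRTC1 replicates 2, 3 and 4 lay at 7.40, 7.45 and 7.23, and the controls of those numbers at 7.16, 7.02 and 6.92. Each CRTC1 array thus lay above the control of the same number, although the labels do not state a pairing.

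Target genes of NF-kB, a transcription factor of inflammatory responses, passed in camera as higher (adjusted p = 1.73e-06), with an adjusted p = 0.341 with an estimated correlation. Of 17 members 16 were higher, with a median log2 change of 0.32. The cytokine genes IL6, CXCL2 and CXCL8 had log2 changes of 0.51, 0.39 and 0.71, and TNFAIP3, an inhibitor of NF-kB, 0.44. Of the members, 5 were higher at an unadjusted p under 0.05, but none passed over all genes or adjusted over the list alone (lowest adjusted p = 0.0819). The list mean per array was 6.10 ± 0.0568 against 5.81 ± 0.108 (SD, n = 4), and all 4 CRTC1 arrays lay above all 4 control arrays (exact permutation p = 0.0286, 0.237 after adjustment over the 29 lists).

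The circadian clock list passed in camera as higher by a small amount (adjusted p = 0.0445), but with an adjusted p = 0.728 with an estimated correlation. Of 16 members 12 were higher, with a median log2 change of 0.08. PER2, a transcriptional repressor of the clock, had a log2 change of 0.43 and NFIL3, a clock output repressor, 0.57. Both passed adjusted over the list alone (adjusted p = 0.0198 and 0.0309) and neither passed over all genes or over the fixed lists together. RORA had 0.34 and DBP 0.22, and 3 members in all were higher at an unadjusted p under 0.05. The call was lost without CRTC1 replicate 1 (adjusted p = 0.498) or empty vector replicate 2 (0.0787), 3 (0.0918) or 4 (0.340). The median was close to 0 without CRTC1 replicate 1, at 0.0087, and was 0.04 without empty vector replicate 3 or 4 and 0.13 without CRTC1 replicate 3.

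Components of the CRTC and CREB pathway, CRTC1 left out, passed in camera as higher by a small amount (adjusted p = 0.0350), against an adjusted p = 0.813 with an estimated correlation. Of 17 members 14 were higher, with a median log2 change of 0.07. The salt-inducible kinase gene SIK2 had a change of 0.31 and was the 1 member at an unadjusted p under 0.05. The histone acetyltransferase genes EP300 and CREBBP had 0.19 and 0.15, and CRTC3 0.19. None passed over all genes or adjusted over the list alone. The list's call was lost without CRTC1 replicate 1 (adjusted p = 0.498) or empty vector replicate 2 (0.0854) or 4 (0.199). The median was 0.04 without CRTC1 replicate 1, 0.12 without CRTC1 replicate 3 and 0.11 without CRTC1 replicate 4.

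Both cell cycle lists passed in camera as lower with CRTC1, by small amounts. The adjusted p was 0.0149 for G1/S, against an adjusted p = 0.830 with an estimated correlation, and 0.0350 for G2/M, against an adjusted p = 0.838 with an estimated correlation. In the list of G1/S and DNA replication genes 18 of 22 members were lower, 2 of them at an unadjusted p under 0.05, with a median log2 change of -0.08. The replicative helicase genes MCM7 and MCM4 had log2 changes of -0.19 and -0.16, the sliding clamp gene PCNA -0.20 and the transcription factor gene E2F1 -0.16. In the G2/M list 19 of 25 members were lower, 1 at an unadjusted p under 0.05, with a median of -0.05. Among 10000 random lists matched on level the G1/S median lay at percentile 0.59 and the G2/M median at percentile 11.02, so the G2/M shift lay within the range common for genes of that level. BIRC5 had -0.19, the ubiquitin-conjugating enzyme gene UBE2C -0.15, and the cyclin genes CCNB1 and CCNA2 both -0.13. No member of either list passed over all genes or adjusted over its list alone. The G1/S call was lost without CRTC1 replicate 1 (adjusted p = 0.221) or empty vector replicate 2 (0.0787) or 4 (0.0869), and the G2/M call without CRTC1 replicate 1 (0.498) or empty vector replicate 1 (0.0542), 2 (0.188) or 4 (0.0903). The G1/S median was -0.05 without CRTC1 replicate 1.

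**Figure D3:**
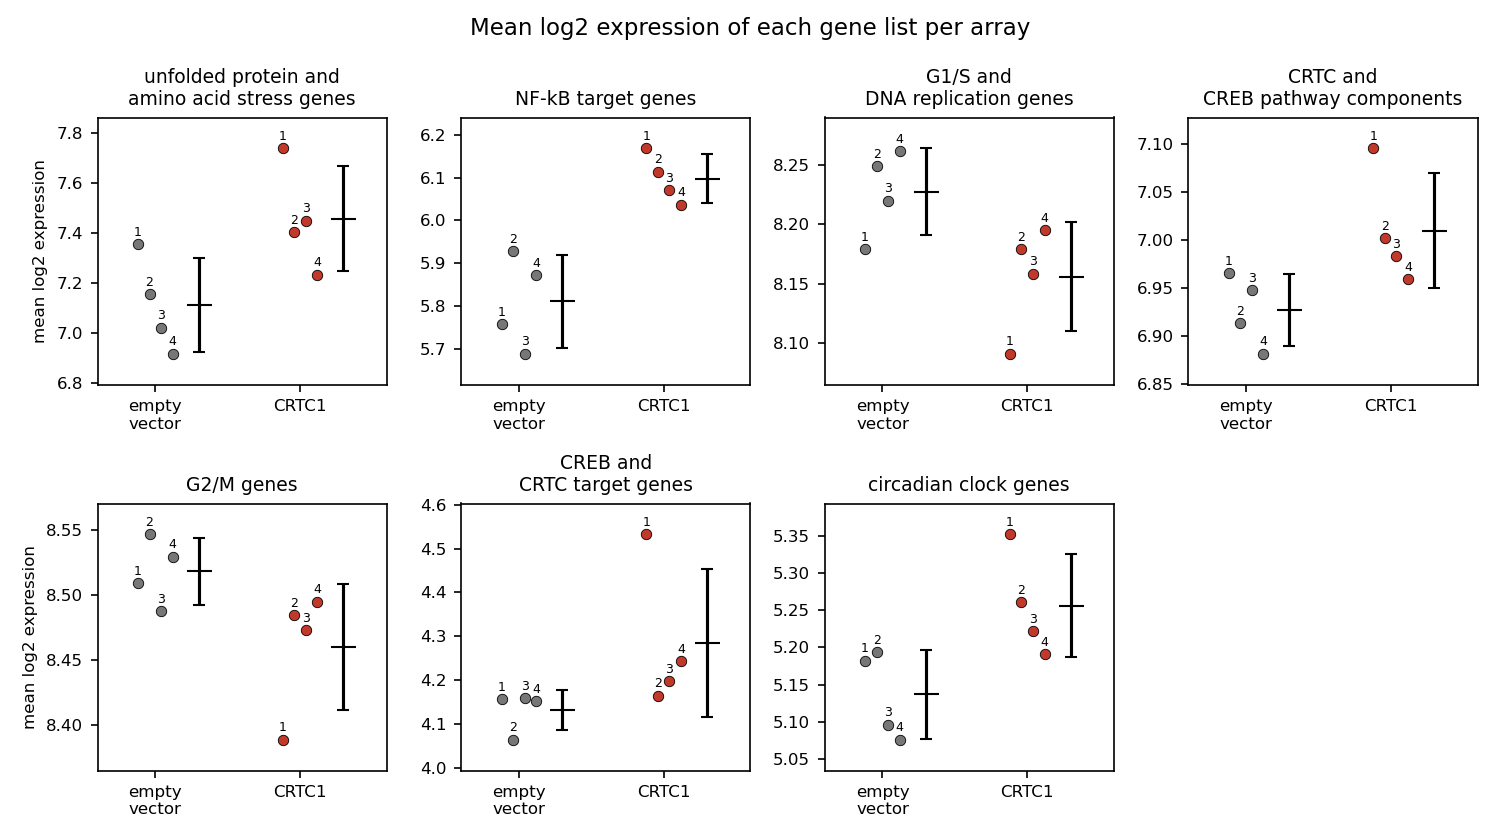
Mean log2 expression of the members of the 7 lists past the threshold in camera, per array, empty vector in grey and CRTC1 in red, with the replicate number above each point and the group mean ± SD (n = 4). The NF-kB list means lay between 6.04 and 6.17 with CRTC1 and between 5.69 and 5.93 with empty vector, and CRTC1 replicate 1 was the extreme array in all 7 lists.

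The remaining 22 lists did not pass in camera, and their medians lay between -0.06 and 0.06. Markers of intestinal and other cell types were among them. Enterocyte markers (adjusted p = 0.490) had 8 members higher and 15 lower, with the apolipoprotein gene APOC3 at -0.27. Goblet cell markers (adjusted p = 0.623) included AGR2 at 0.12, and enteroendocrine markers (adjusted p = 0.591) the ghrelin gene GHRL at 0.18. Leukocyte markers (adjusted p = 0.567) included FCER1G at -0.31, and endothelial markers (adjusted p = 0.865) CLDN5 at 0.33. Among fibroblast markers (adjusted p = 0.874) PDGFRB had a log2 change of 0.42 at a mean level of 2.95 with CRTC1. It was the 1 member to pass adjusted over the list alone (adjusted p = 0.0365), but not over the fixed lists together. Wnt target and crypt stem genes (adjusted p = 0.623) included RNF43 at -0.17.

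The remaining stress, metabolic and signalling lists did not pass in camera with all 8 arrays. Heat shock genes had an adjusted p of 0.931, with HSPA1A at -0.20, and NRF2 and oxidative stress genes 0.591, with the cystine transporter gene SLC7A11 at 0.49. Without empty vector replicate 1 the NRF2 list passed as higher in camera at the preset correlation (adjusted p = 0.0285). With all 8 arrays and an estimated correlation its adjusted p was 0.838. Hypoxia and glycolysis genes had 0.865, with EGLN3 at 0.55, p53 targets 0.649, with MDM2 at 0.27, and metallothionein genes 0.623, with MT1G at -0.25. The adjusted p was 0.490 for oxidative phosphorylation, where CYC1 was at -0.10, 0.865 for cholesterol synthesis, where MVK was at -0.22, and 0.591 for bile acid and FXR genes, where FABP6 was at -0.29. For cAMP-regulated ion transport genes it was 0.591, with the sodium-proton exchanger gene SLC9A3 at -0.37. Growth factor and MAPK response genes had 0.649, with JUN at 0.50, and interferon-stimulated genes 0.596, with BST2 at 0.37. Ribosomal protein genes had 0.623, with RPS20 at -0.15, and replication-dependent histone genes 0.623, with H3C1 at -0.35. Junction genes had 0.931, with CTNNB1 at -0.16, and genes of epithelial-mesenchymal transition 0.983, with ZEB1 at -0.20. The list median, mean and camera direction differed in sign for the growth factor, endothelial, hypoxia, fibroblast, heat shock and epithelial-mesenchymal transition lists.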

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

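Of 164 groups of 4 arrays tested for an array far from the other 3, 8 had one by Dixon's test, and chance gives about 8. The tests were chosen before the data were examined. PLSCR2 lay at 2.59 on CRTC1 replicate 3, against 2.24 to 2.27 on the other CRTC1 arrays. KDM3A lay at 6.80 on CRTC1 replicate 2, against 6.961 to 6.975. PDGFRB lay at 2.85 on the same array, against 2.97 to 2.99. GHRL lay at 3.01 on CRTC1 replicate 4, against 2.90 to 2.92. CCNA2 lay at 9.45 on CRTC1 replicate 1, against 9.67 to 9.70, and CYC1 at 9.57 on that array, against 9.83 to 9.88. PER2 lay at 4.48 on empty vector replicate 4, against 4.72 to 4.73 on the other control arrays. The mean of the CREB and CRTC target list lay at 4.06 on empty vector replicate 2, against 4.15 to 4.16.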

How the results depend on the processing

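CRTC1 stayed past the threshold in each alternative run, with a log2 change between 5.61 and 6.20. Genes past the threshold numbered 2, both higher, with a variance trend and robust moderation, which added H3C4 (adjusted p = 0.0235, range over the alternatives 0.0235 to 0.934). Genes at an unadjusted p and 1.5-fold numbered 21 at or above the median level, where fewer and brighter genes were tested, and 97 to 162 with 1 array or 1 replicate number left out. The log2 change of CRTC2 ran from -0.0409 (without CRTC1 replicate 1) to 0.125 in those fits, and was -0.0124 without replicate 1. Lists past the threshold numbered 3 with array weights, 0 with an estimated correlation and 0 with fry. With arrays left out they numbered 2 to 7, and the lowest, 2, came without CRTC1 replicate 1, empty vector replicate 2, replicate 1 or replicate 2. The stress and NF-kB lists passed in 20 of 22 alternatives, all but the estimated correlation and fry. The NRF2 list passed in camera at the preset correlation without empty vector replicate 1 (adjusted p = 0.0285). Its adjusted p was 0.838 with all arrays and an estimated correlation. The causes were not tested. Of 1496 values of named genes, 1493 kept their direction and side of the threshold. None of these 73 genes had passed and many were chosen for a small p, so this was likely from the start. Of 632 list values 575 kept their side, 38 of them, from lists that did not pass, with the other direction. The 7 lists lost the threshold in 56 values. Among these were the CREB and CRTC target list (camera adjusted p = 0.0687) and the G2/M list (0.195) with quantile normalization. The labels do not say what arrays with equal replicate numbers share. Correlations of same-numbered deviations were 0.251, 0.0385, 0.0639 and 0.117, and 8 of 8 arrays correlated best with their own number in the other group. This is a hint of pairing from the data, not the design, and the main fit and the exact permutations leave it out. With the number as a block, CRTC1 was again the 1 gene past the threshold in limma (adjusted p = 0.0303). In that fit 1677 genes had an unadjusted p under 0.05, against 1333 in the main fit, and 86 also differed at least 1.5-fold. The same 7 lists passed in camera at the preset correlation, with 2.92e-09 the higher adjusted p of the stress and NF-kB lists. Camera with an estimated correlation and fry were not run with the block. Averaging probe sets per gene and testing single CRTC1 probe sets were not run, since each gene had 1. Without detection calls, limits set by background are unknown.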

Other observations

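The second lists below and their values with an array left out were chosen after the fixed-list results were seen, as were the tests of correlated genes, of CRTC1 replicate 1 and of the replicate block, while the other tests were chosen before their results. A second list of ER chaperone and degradation genes, sharing no gene with the first, had 18 of 22 members higher and 4 lower with CRTC1. EDEM1, a lectin of ER-associated degradation, had a log2 change of 0.38, the co-chaperone gene DNAJC3 0.34, the ER chaperone gene HYOU1 0.29 and the disulfide isomerase gene PDIA4 0.21. None of these 4 genes passed over all genes (adjusted p = 0.837 in limma). The list mean per array was 8.44 ± 0.109 against 8.29 ± 0.0642 (SD, n = 4), with camera's adjusted p at 4.66e-05 over 3 second lists and an adjusted p = 0.368 with an estimated correlation. With each array left out in turn, the difference in list means ran from 0.09 to 0.18 for this list and from 0.05 to 0.14 for a second amino acid list. For a second NF-kB list it ran from -0.02 to 0.09, and it turned below 0 without CRTC1 replicate 1. The lowest values of the other lists also came without that array. CRYAB, a small heat shock protein gene chosen after its values were seen, reached 3.71 ± 0.840 (SD, n = 4) with CRTC1. Its log2 change of 1.21 from the controls was the third in size and did not pass (adjusted p = 0.837).

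A candidate explanation for the single gene past the threshold is that smaller changes were missed. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many as 1 gene, and 1 as many genes higher, with 0 the highest of the others, but that gene is the transfected CRTC1, so this count tests nothing about chance for other genes. For genes lower, 35 of 35 splits gave 0. For genes at an unadjusted p and 1.5-fold chance cannot be excluded, since 14 of 35 splits gave at least 81, the highest other 160. Of the 14, 12 put both replicate 1 arrays on the same side, which points to a structure of the samples. The count over all splits is therefore not a clean measure of chance. Besides the real split, those with 1 array of each number on each side gave 54 to 72, a comparison made afterwards on few splits. Simulated 1.5-fold changes were recovered at 47.5%, within the spread between runs of the bound set in advance, so this test leaves open how many such changes were missed. Each run held 200 changed genes, which eases the adjusted threshold, so recovery may be lower in data where 1 gene passed.

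The 7 lists past the threshold in camera were more than in any other split of the arrays. Of 35 splits 1, the real one, gave as many, and the highest other gave 6. The split with 6 set CRTC1 replicates 1, 2 and 3 and empty vector replicate 1 against the rest, so it shared much of the real grouping. Besides the real split, those with 1 array of each number on each side gave 0 to 2, a comparison made afterwards. Over all 35 splits the real one ranked first, but 1 in 35 is the smallest share that test can give. Chance for the count at the preset correlation is therefore less likely but not excluded. The count also fell to 2 without CRTC1 replicate 1 or without empty vector replicate 2. With a correlation estimated from the data 0 lists passed. That would follow if genes of a list vary together between arrays by more than the preset value of 0.01. The estimate was 0.524 for the stress list and 0.0970 for NF-kB targets. It came from the fit without the replicate number, so variation shared by arrays of the same number counts in it. How much that adds was not tested.

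The higher stress and NF-kB lists may reflect a response to CRTC1, and the tables argue against 1 technical explanation, a trend with signal level, since both medians were at percentile 100 among 10000 random lists matched on level. CRTC1 replicate 1 was the array farthest from the others on the first principal component. The test set for whether it carries the pattern alone was not decided. Without it the difference in list means kept 72.6% of its size for stress genes and 91.7% for NF-kB targets. All 3 other CRTC1 arrays lay above the mean of the controls, but the exact permutation p was 0.114 and 0.0571, where 0.0286 is the smallest possible. That test kept empty vector replicate 1, the highest control for stress genes, at 7.35. Without both replicate 1 arrays the list medians were 0.26 for stress genes and 0.23 for NF-kB targets, against 0.27 and 0.32 with all arrays. The remaining CRTC1 arrays had stress list means of 7.23 to 7.45, against 6.92 to 7.16 in the remaining controls. For NF-kB targets they had 6.04 to 6.11, against 5.69 to 5.93. These values argue against CRTC1 replicate 1 alone carrying the 2 fixed lists, though it may add to their size. Whether the response is wider stays open: exact permutation p-values were 0.0857 for the second ER chaperone list, 0.229 for the second amino acid list (difference 0.10) and 0.657 for the second NF-kB list (difference 0.04, turning to -0.02 without CRTC1 replicate 1). No arm expressed another protein, so a response to the load of any expressed protein, rather than to CRTC1, was not tested and stays open.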
